A study of Danio rerio with 4 samples.

How the data were processed

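Total RNA from zebrafish (Danio rerio) that received a morpholino, an antisense oligonucleotide that blocks translation or splicing of its target, was measured on 4 expression arrays. Per the labels, 2 arrays carried RNA from the nck2 morpholino group and 2 carried RNA from a control morpholino group, and within each group the arrays are lettered A and B as hybridizations. No label says whether A and B came from separate clutches or embryos, so the p-values measure only the spread between these arrays, which may be technical. Developmental stage, morpholino sequence and dose, and hybridization or scan dates are not given in the sources used here.

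The authors deposited 1 linear intensity per probe set on each array, for 15617 probe sets of an Affymetrix zebrafish array. The 2% trimmed mean of the deposited intensity was 2500 on every array, which shows that the arrays had been scaled to a common target before deposit. The scanner software, the method that summarised the probes and the detection calls are not given in the sources used here. Scaling to a common mean forces the average intensity to be equal, so a change shared by most transcripts cannot be seen in these values. All columns of the table of values were mapped to a labelled sample.

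Probe sets were named through the platform's probe table, with symbols updated through Entrez gene numbers against a current zebrafish RefSeq gene table (assembly GRCz12tu). That gene table was used for names alone, and no coordinates were taken from it. Of the probe sets, 115 were array controls and were left out of all tests. Of the other 15502, 10795 had 1 gene symbol, 135 had several and 4572 were unnamed here. The named probe sets covered 8793 genes, 10711 probe sets were matched by Entrez number, and 1 symbol was updated. A probe set with several symbols was never used to name a gene.

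Intensities were converted to log2 without an added offset. Probe sets whose mean log2 intensity over the 4 arrays was at or above the 40th percentile, an intensity of 724, were tested, which left 9301 probe sets. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean intensity), with group as the only term and 2 residual degrees of freedom, to which the empirical Bayes step added 12.3 prior degrees of freedom. The tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the probe sets tested, and an adjusted p under 0.05 was called a change. Every log2 difference is nck2 morpholino minus control morpholino, and its error is the limma standard error (SE). Means of intensity are given with the SD over 2 arrays. The number of arrays limits the precision of every value.

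Background was read from 17 tag control probe sets, which match no zebrafish transcript, as their 95th percentile on each array. Where both arrays of a group lay below it, the difference is given as "at least N-fold", which sets the mean log2 level of the brighter group against the mean of, per array, the higher of the background level and the measured value.

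For gene lists, the brightest probe set of each gene was used, giving 6115 genes. In all, 33 lists of zebrafish genes were written down beforehand. Of these 1, which is counted among the lists that shifted, is not reported here, and the others were interferon and antigen presentation, heat shock and chaperones, immediate early genes, Nck partners and actin regulators, axon guidance and ephrin signalling, endothelium, erythroid cells, myeloid cells, skeletal muscle, heart, differentiated neurons, neural progenitors and regional patterning, lens crystallins, retina and pineal photoreceptors, neural crest and pigment cells, notochord and floor plate, tailbud and presomitic mesoderm, hatching gland, epidermis and ionocytes, liver, yolk layer and plasma proteins, exocrine pancreas, intestine and endocrine pancreas, kidney, cartilage, bone and extracellular matrix, cell cycle and DNA replication, germline and maternal genes, hypoxia and glycolysis, sterol synthesis, circadian clock, proteasome, cytosolic ribosomal proteins and oxidative phosphorylation. Lists with at least 5 genes tested were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 28 lists that qualified. The same test with a correlation estimated for each list, and fry, which asks whether the genes of a list move one way on balance, were run as alternatives.

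The genes named in the text follow a fixed rule. It took every probe set of nck2 and nck1 genes. It also took up to 12 genes per direction with the largest absolute log2 difference among probe sets past the threshold whose nck2 arrays both lay on the same side of both control arrays, with 1 gene symbol that is not a bare clone name. For each list described it took up to 4 members with the smallest p. Where other genes are named, the text says that they were chosen after their values were seen.

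The grouping, the tests, the filter, the lists and the rule for named genes were chosen before the data were examined. So were these alternatives: quantile normalization, centring on the median, an offset of 50, no filter, a filter at the 60th percentile, eBayes without the trend, robust eBayes, the hybridization letter as a block, leaving out each array in turn, and the mean of all probe sets of a gene. Cyclic loess normalization and leaving out probe sets that can match several transcripts were chosen after seeing the data. The fit was tested on simulated data with the 9301 probe sets, of which 200 were changed per run over 10 runs. The simulated noise was independent between probe sets and arrays, with a spread that followed only the trend on mean intensity in these arrays. The fit recovered 42.9% of changes of 0.5 and 93.2% of changes of 1 on the log2 scale, and 2.89% of its calls were false. These rates apply to that setting and are not the error rate of calls in the real data. With 13 simulated lists shifted by 0.3, camera recovered 13 with the preset correlation and 0 with an estimated correlation. The simulated genes of a list varied independently, a condition close to the preset correlation. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for naming probe sets and drawing the plots.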

Results

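RNA levels were compared between zebrafish given an nck2 morpholino and zebrafish given a control morpholino, with 2 arrays in each group. The nck2 gene encodes an adaptor protein of SH2 and SH3 domains that links tyrosine kinase receptors to the actin cytoskeleton. Median intensity was 1057 and 1010 on the nck2 arrays A and B, and 1155 and 1165 on the control arrays A and B. Between 63.3% and 69.5% of probe sets lay above background on each array. Over the probe sets tested, log2 intensities of the 2 arrays of a group had a Pearson r of 0.982 (nck2) and 0.986 (control), and those of arrays from different groups had an r of 0.951 to 0.958. The SD of the log2 difference was 0.29 and 0.25 within the groups and 0.44 to 0.48 between them. The array's control probe sets at the 3' and 5' ends of GAPDH gave a 3' to 5' intensity ratio of 1.42 ± 0.0128 (SD, n = 2) in nck2 and 1.22 ± 0.0168 (SD, n = 2) in control arrays. The same ratio for acta1, a muscle actin, was 3.75 ± 0.621 (SD, n = 2) in nck2 and 4.06 ± 0.195 (SD, n = 2) in control arrays.

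The transcripts of nck2a and nck2b did not pass the test, and the labels do not say whether the morpholino targets nck2a, nck2b or both. The nck2a probe set had an intensity of 1966 ± 76.0 (SD, n = 2) in nck2 and 1601 ± 12.4 (SD, n = 2) in control arrays, a log2 difference of 0.30 (SE 0.17, 95% interval -0.06 to 0.66, limma adjusted p = 0.223). With each array centred on its median, the nck2a difference was 0.47 (limma adjusted p = 0.0493). The brighter nck2b probe set differed by 0.19 (SE 0.23, limma adjusted p = 0.586). The dimmer nck2b probe set lay below the intensity filter, at 335 ± 77.8 (SD, n = 2) in nck2 and 629 ± 37.1 (SD, n = 2) in control arrays. Both nck2 arrays and 1 control array lay below background there, so no fold is given, and the difference did not pass (limma adjusted p = 0.157 in a fit without the filter). The related genes nck1a and nck1b differed by 0.33 (SE 0.25, adjusted p = 0.368) and 0.06 (SE 0.12, adjusted p = 0.753). A morpholino that blocks translation need not lower its target's transcript, so these values do not test the labels.

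The genes that rose most in the nck2 morpholino group included phlda3, rps27l, ccng1 and genes of muscle, while those that fell most included a plasma complement protein and genes of glycolysis and the hypoxia response. The gene phlda3, an inhibitor of Akt signalling, had an intensity of 4505 ± 75.9 (SD, n = 2) in nck2 against 544 ± 51.3 (SD, n = 2) in control arrays, where it lay below background, and was at least 7.53-fold higher (limma adjusted p = 9.5e-08). The ribosomal protein-like gene rps27l and the cyclin G gene ccng1 rose by 1.87 (SE 0.11) and 1.62 (SE 0.10) on the log2 scale. In the other direction, chpt1, which encodes a choline phosphotransferase of phosphatidylcholine synthesis, was 15.6-fold lower, at 551 ± 65.3 (SD, n = 2) in nck2 and 8579 ± 670 (SD, n = 2) in control arrays (log2 difference -3.96, SE 0.16, limma adjusted p = 4.3e-09). Its intensity on nck2 arrays A and B was 505 and 597, close above their background of 487 and 517, so the size of this fold rests on values near background. The complement component c9 fell on all 3 of its probe sets, with a log2 difference of -3.10 (SE 0.19) on the one that fell most. That probe set can match several transcripts, and the brightest c9 probe set differed by -2.82 (SE 0.14).

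Of 9301 probe sets tested, 2185 (23.5%) changed, 914 of them higher and 1271 lower in nck2, and 3336 had an unadjusted p under 0.05. At least 2-fold changes were found for 46 higher and 164 lower probe sets. The higher probe sets belonged to 731 named genes and the lower ones to 873, with 4 genes in both. Both nck2 arrays lay on the same side of both control arrays for 5823 probe sets (62.6%), where chance gives 33.3% if all arrays vary independently. The labels do not say whether arrays A and B are repeat hybridizations of the same RNA. If they are, any difference between the RNA samples would raise this share, so the contrast with chance does not test an effect of nck2. The balance of directions depended on the scaling between arrays. Higher calls made up 41.8% with the deposited scaling, 50.2% with quantile normalization (986 higher, 977 lower), 49.2% with cyclic loess (988 higher, 1021 lower) and 72.3% with median centring (1878 higher, 718 lower), which moved the median difference of all tested probe sets by 0.17. Without control array A the count of changed probe sets was 571, and without control array B it was 639.

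Among the other genes that rose most, lnx1, a ubiquitin ligase, was at least 3.36-fold higher (limma adjusted p = 7.7e-05) and fosab, the immediate early transcription factor c-Fos, was at least 2.56-fold higher on 1 probe set (limma adjusted p = 0.000387), with both control arrays below background on the probe set of each. The other fosab probe set rose by 0.94 (SE 0.26, limma adjusted p = 0.0198), or 1.91-fold, with 1 control array below background. The calcium-binding parvalbumin pvalb3 rose by 1.57 (SE 0.12) and the muscle Z-disc gene ldb3a was 2.64-fold higher (SE 0.13 on the log2 scale). The immunoproteasome subunit psmb10 rose by 1.45 (SE 0.21) and the ribosome assembly factor mak16 by 1.44 (SE 0.14). The gene lemd1 was 2.82-fold higher (SE 0.13 on the log2 scale) and bmb rose by 1.48 (SE 0.21), with 1 control array below background for bmb. On 1 probe set rer1, a retrieval receptor of the endoplasmic reticulum, rose by 1.46 (SE 0.11), while its other probe set differed by -0.22 and did not pass.

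Among the other genes that fell most, egln3, a hypoxia-inducible prolyl hydroxylase that marks hypoxia-inducible factor for degradation, was at least 5.33-fold lower and lay below background on both nck2 arrays (limma adjusted p = 8.8e-07). The gluconeogenic enzyme gene pck1 was at least 4.37-fold lower, also with both nck2 arrays below background (limma adjusted p = 1.3e-05). Lactate dehydrogenase ldha fell by 1.87 (SE 0.24) and the collagen prolyl hydroxylase p4ha1b by 1.75 (SE 0.12) on the log2 scale. The actin regulator vaspb fell on 4 of 4 probe sets, of which 3 differed by -1.04 to -1.38. The named one was below background on 1 nck2 array, and at least 2.82-fold lower with that array at the background level (limma adjusted p = 0.00386). That vaspb probe set had an adjusted p of 0.0863 without control array A, 0.0553 without control array B, 0.0513 without the variance trend and 0.161 with robust eBayes. The genes a2m2e, cox6b1 and thumpd3 differed by -2.44 (SE 0.14), -2.31 (SE 0.16) and -2.15 (SE 0.20). The keratin krt91 fell on 2 of 2 probe sets, and the named one, which differed by -2.16 (SE 0.21), can match several transcripts and lay below background on 1 nck2 array. On 1 probe set sypl2a differed by -2.17 (SE 0.21), while its other probe set differed by -0.14 and did not pass.

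**Figure D1:**
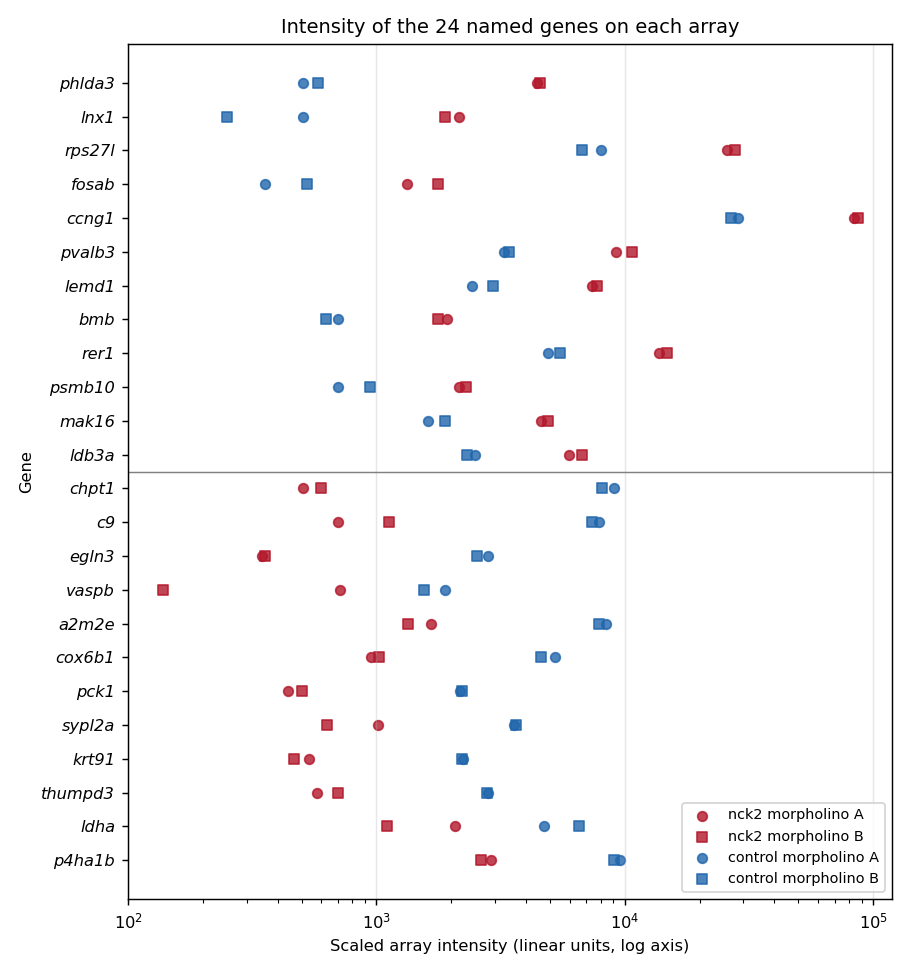
Scaled intensity (linear units on a log axis) of the 12 named genes that were higher and the 12 that were lower in the nck2 morpholino group, with 1 point per array, red for nck2 and blue for control, circles for array A and squares for array B. The nck2 and control points of every gene shown are separated, and chpt1 has means of 551 in nck2 and 8579 in control arrays.

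Of 28 gene lists tested, 5 shifted up and 5 shifted down in nck2. With an estimated correlation between genes, 0 lists passed camera, with a lowest adjusted p of 0.282 and 4 lists at an unadjusted p under 0.05. The alternative fry called 20. In simulated data the estimated correlation recovered none of the shifted lists. The simulated genes varied independently, so the simulation cannot tell which setting holds where genes of a list vary together. Estimated correlations were 0.254 for oxidative phosphorylation, 0.112 for the liver list and 0.108 for the proteasome, against the preset of 0.01. They were -0.0076 for axon guidance and -0.0085 for neural progenitors, below the preset, yet both lists lost their calls. A call lost with an estimated correlation therefore does not by itself show that the genes of a list varied together.

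The oxidative phosphorylation and proteasome lists shifted up. Of 75 genes of oxidative phosphorylation, 47 rose and 1 fell (58 and 1 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 1.6e-16, adjusted p = 0.384 with an estimated correlation). The complex I genes ndufa12 and ndufab1b rose by 0.84 (SE 0.12) and 0.62 (SE 0.11), and the cytochrome oxidase gene cox7a2a rose by 0.67 (SE 0.10). The gene that fell was cox6b1, at -2.31. Of 35 proteasome genes, 25 rose and 1 fell (27 and 1 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 4.6e-13, adjusted p = 0.309 with an estimated correlation). Examples were psmb3, at 0.76 (SE 0.10), psmd3, at 0.79 (SE 0.10), and psmb4, at 0.75 (SE 0.10). The proteasome gene that fell was psmc1b, at -0.67, named after its value was seen.

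Skeletal muscle genes were higher as a list, with a median of 0.40 over 40 genes (camera adjusted p = 3.6e-11, adjusted p = 0.282 with an estimated correlation). In this list 23 rose and 2 fell (27 and 3 adjusted over the list alone). The calcium-binding pvalb1 rose by 1.23 (SE 0.10), while myog, the myogenin transcription factor that drives muscle differentiation, fell by 1.25 (SE 0.13). The other muscle gene that fell was the transcription factor mef2ca, at -0.53, named after its value was seen. Heat shock and chaperone genes shifted up with a median of 0.37 over 16 genes, 9 higher and 2 lower (10 and 3 adjusted over the list alone, camera adjusted p = 0.00915, adjusted p = 0.331 with an estimated correlation). The chaperones hsp90aa1.2 and hspd1 rose by 0.90 (SE 0.13) and 0.58 (SE 0.10). In contrast, the inducible hsp70.3 fell by 1.51 (SE 0.19), on a probe set that can match several transcripts. The chaperone gene dnajb1b, named after its value was seen, also fell, at -0.45. The heat shock call was lost with quantile normalization (camera adjusted p = 0.1004) and with cyclic loess (camera adjusted p = 0.0985).

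The neural progenitor and axon guidance lists shifted down. Of 44 genes of neural progenitors and regional patterning, 0 rose and 17 fell (0 and 19 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 1.9e-06, adjusted p = 0.282 with an estimated correlation). With median centring, which moves every gene alike, the neural progenitor median was -0.15. The receptor notch3 fell by 1.22 (SE 0.16), the radial glial fabp7a by 0.89 (SE 0.10), the Notch ligand dla by 0.66 (SE 0.12) and sox11b by 0.62 (SE 0.10). Of 25 genes of axon guidance and ephrin signalling, 0 rose and 17 fell (0 and 18 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 3.1e-06, adjusted p = 0.282 with an estimated correlation). The ephrin receptor epha4b fell by 1.01 (SE 0.14), and the ephrins efnb2a and efnb3b by 0.85 (SE 0.17) and 0.88 (SE 0.19). In contrast, the 34 genes of differentiated neurons gave 2 higher and 3 lower (2 and 3 adjusted over the list alone), with a median of 0.01 (camera adjusted p = 0.900). Their mean was -0.02, opposite in sign to the median.

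Genes of hypoxia and glycolysis shifted down, with a median of -0.38 over 26 genes (camera adjusted p = 0.000961, adjusted p = 0.331 with an estimated correlation). In this list 11 fell and 3 rose (12 and 3 adjusted over the list alone). With median centring the hypoxia median was -0.21. Beside egln3, the glycolytic gpia fell by 1.56 (SE 0.13) and pfkfb4b, an activator of glycolytic flux, by 1.16 (SE 0.12). The genes that rose were eno3, the muscle enolase and also a member of the muscle list, at 0.95 (SE 0.10), and gapdh and aldoab, at 0.54 and 0.43, both named after their values were seen. The GAPDH control probe sets, annotated to gapdhs of this list, differed by -0.57 at the 3' end, -0.73 in the middle and -0.79 at the 5' end.

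Genes of the liver, yolk layer and plasma proteins shifted down, with a median of -0.22 over 38 genes (camera adjusted p = 0.000998, adjusted p = 0.471 with an estimated correlation). In this list 15 fell and 1 rose (15 and 2 adjusted over the list alone). The liver list's median was -0.05 with median centring and -0.31 with quantile normalization. Beside c9, the plasma protein gene ambp fell by 1.47 (SE 0.13), the apolipoprotein apoc2 by 0.97 (SE 0.10) and the complement gene c3a.1 by 0.98 (SE 0.12). The gene that rose was the iron exporter slc40a1, at 0.37, named after its value was seen. Genes of intestine and endocrine pancreas also shifted down, with a median of -0.50 over 8 genes, 0 higher and 4 lower by either adjustment, all genes tested or adjusted over the list alone (camera adjusted p = 0.00523, adjusted p = 0.331 with an estimated correlation). Beside pck1, the fatty acid carrier fabp1b.1 fell by 0.59 (SE 0.10) and pax6b by 0.61 (SE 0.17). The gene pax6b is also a member of the neural progenitor list. The members neurod1 and isl1a, also in the differentiated neuron list, and apoa4a, also in the liver list, were named after their values were seen. This list is therefore not independent of the others. The intestine and endocrine pancreas median was -0.33 with median centring, and the call was lost with a filter at the 60th percentile (median -0.27, camera adjusted p = 0.0633).

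**Figure D2:**
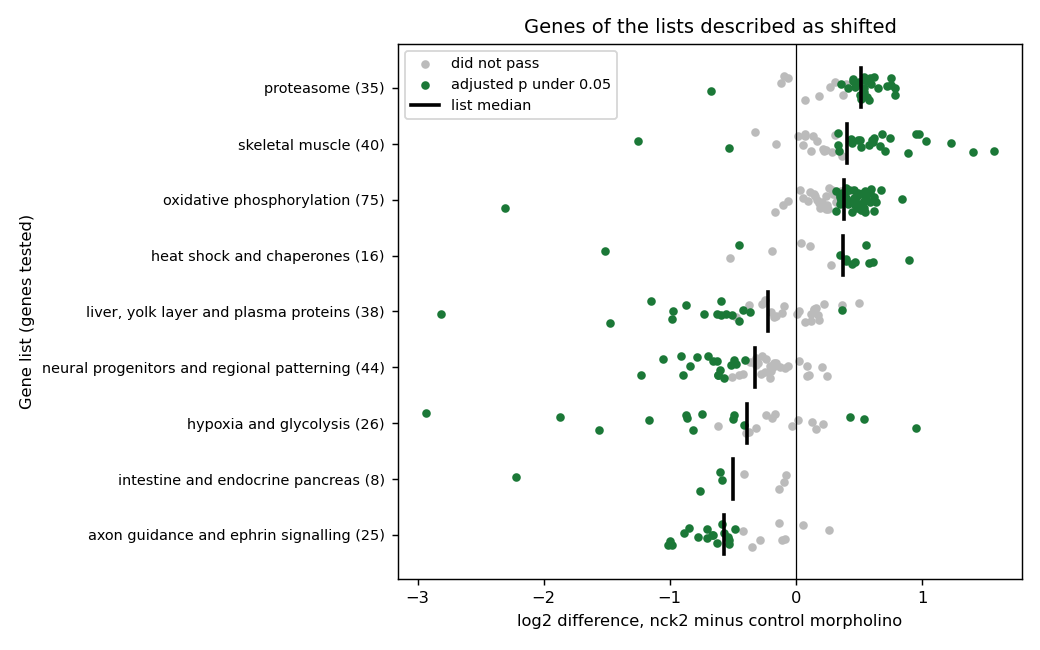
log2 difference (nck2 minus control morpholino) of each gene in the gene lists described as shifted, with the number of genes tested in brackets, green for genes past the threshold, grey for the others and a black bar at the list median. The medians range from 0.52 for the proteasome to -0.57 for axon guidance and ephrin signalling, and every list holds genes that did not pass.

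The partners of Nck and other actin regulators did not pass camera as a list (median -0.07 over 37 genes, camera adjusted p = 0.4999, fry adjusted p = 0.0482), with 5 higher and 7 lower (6 and 7 adjusted over the list alone). Its members moved in both directions: gelsolin gsnb fell by 1.31 (SE 0.15) and the Arp2/3 complex genes arpc5b and arpc3 rose by 0.46 (SE 0.10) and 0.44 (SE 0.10), while arpc1b of the same complex, named after its value was seen, fell by 1.01 (SE 0.23). The circadian clock list had a median of -0.37 over 15 genes, with 0 higher and 4 lower (0 and 6 adjusted over the list alone), and did not pass (camera adjusted p = 0.0522). It passed with median centring (adjusted p = 0.0392), with the mean of all probe sets of a gene (adjusted p = 0.0493), without nck2 array B (adjusted p = 0.0384) and without control array B (adjusted p = 0.0213). Among clock genes, cry4 fell by 0.99 (SE 0.22) and bmal2 by 0.82 (SE 0.24). Epidermis and ionocytes (median -0.14 over 46 genes, 6 higher and 12 lower, 6 and 13 adjusted over the list alone, camera adjusted p = 0.177) held the keratin krt17, which fell by 1.57 (SE 0.11), and anxa1a, which rose by 0.73 (SE 0.10). Neural crest and pigment cells had a median of -0.21 over 14 genes, 0 higher and 4 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.177), and foxd3 and snai2 fell by 0.55 (SE 0.15) and 0.54 (SE 0.16). The epidermis and neural crest lists passed as lower with quantile normalization (adjusted p = 0.00598 and 0.0370), with cyclic loess (adjusted p = 0.00832 and 0.0358) and with fry (adjusted p = 0.0482 and 0.0377).

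Markers of other cell types did not pass camera as lists. With fry, which does not compare a list with other genes, endothelium (adjusted p = 0.0260), heart and tailbud (adjusted p = 0.0209 for each), kidney (adjusted p = 0.0474), and myeloid, notochord and immediate early genes (adjusted p = 0.0482 for each) passed as lower. The fry test was run with the deposited scaling alone. With median centring, medians were -0.030 for endothelium, 0.001 for heart, -0.034 for tailbud and -0.045 for kidney. They were -0.028 for myeloid, 0.074 for notochord and 0.085 for immediate early genes, so these fry calls may depend on the scaling. Endothelium had 1 gene higher and 4 lower of 10 (camera adjusted p = 0.401), among them kdrl, at -0.69 (SE 0.19), and fli1, at -0.76 (SE 0.19). Erythroid cells had 1 higher and 3 lower of 15 (camera adjusted p = 0.471), myeloid cells 0 and 2 of 8 (camera adjusted p = 0.471), heart 0 and 1 of 11 (camera adjusted p = 0.331), kidney 0 and 2 of 9 (camera adjusted p = 0.263), and hatching gland 0 and 1 of 5 (camera adjusted p = 0.921). Notochord and floor plate had 0 higher and 3 lower of 18 (camera adjusted p = 0.263), and tailbud and presomitic mesoderm 0 and 2 of 15 (camera adjusted p = 0.233). Cartilage, bone and extracellular matrix had 2 higher and 2 lower of 38 (camera adjusted p = 0.921), among which the matrix protease mmp2 was 2.47-fold higher (SE 0.13 on the log2 scale). Cell cycle and DNA replication genes had 6 higher and 7 lower of 71 (camera adjusted p = 0.895), immediate early genes 1 and 3 of 12 (camera adjusted p = 0.471), and sterol synthesis 0 and 1 of 7 (camera adjusted p = 0.900). Cytosolic ribosomal proteins had 2 higher and 2 lower of 72 (camera adjusted p = 0.260), with rps27l the gene that rose most. The ribosomal list passed as lower with cyclic loess (median -0.12, adjusted p = 2.5e-05) and as higher without nck2 array A (median 0.16, adjusted p = 5.2e-05). The sign of the median of the ribosomal, epidermis, erythroid, heart, immediate early, cell cycle, extracellular matrix, notochord and Nck partner lists depended on the scaling. The sterol synthesis list had a median of 0.16 and a mean of -0.06, and hatching gland a median of 0.19 and a mean of -0.02. Adjusted over the list alone, the higher and lower counts were the same for endothelium, erythroid, myeloid, heart, kidney, notochord, extracellular matrix, cell cycle and immediate early genes. They were 0 and 0 for tailbud and for sterol synthesis, 0 and 2 for hatching gland and 1 and 1 for ribosomal proteins.

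The other 5 lists had too few genes above the filter to be tested. Of lens crystallins, cryba4 and crybb1 rose by 0.48 (SE 0.12) and 0.45 (SE 0.11). Of photoreceptor genes, the retinal homeobox genes rx1 and rx2 fell by 0.59 (SE 0.18) and 0.91 (SE 0.21). Of interferon genes, psmb10 rose and b2m differed by 0.64 (adjusted p = 0.0736). The exocrine pancreas and germline lists each had 2 genes tested, of which 0 changed over all genes tested. Adjusted over the list alone, 2 interferon genes and 1 exocrine pancreas gene passed, and the other counts were as above.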

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

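The tests of scaling, of single arrays, of other effects of the morpholino, of developmental stage and of RNA degradation in this part were chosen only after the results were seen, while the test of a trend on brightness was chosen before. The GAPDH control probe sets, which no comparison uses, had a 3' to 5' ratio of 1.42 in nck2 and 1.22 in control arrays, a difference between groups in data outside the main measurement.

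Genes of hypoxia and glycolysis shifted down as a list, with egln3 and ldha among those that fell most. The list median stayed at or below -0.21 under the 3 other scalings, reached with median centring, which moves every gene alike and leaves little margin to the bound of -0.2 set for this test. The list passed camera with quantile normalization and cyclic loess (highest adjusted p = 0.000152), which argues against a scaling that differs with intensity as the whole cause. Against 1 array that stands apart, the list median was at most -0.25 when any array was left out. A response to the morpholino that does not need loss of nck2 cannot be told apart from an effect of nck2, since there was 1 nck2 morpholino group, and a difference in rearing, oxygen or handling was not tested.

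The oxidative phosphorylation and proteasome lists shifted up and the neural patterning and axon guidance lists shifted down, calls that 0 lists kept with an estimated correlation. A trend of the difference on brightness was argued against as the whole cause. The least extreme of the 4 list medians lay at percentile 0, counted from the nearer end, of 10000 random lists matched on mean level. The matched lists had medians of 0.09 for oxidative phosphorylation, 0.10 for the proteasome, -0.01 for neural patterning and -0.09 for axon guidance. Each went in the direction of its list, so brightness may account for a part. With quantile normalization the list medians were 0.29, 0.41, -0.27 and -0.50 in the same order. A difference in developmental stage between the groups cannot be told apart from an effect of nck2, since stage is not labelled and any difference would coincide with group. In the test set for it, the median of differentiated neuron genes was 0.012 and the list passed in neither direction. A shift of that list either way would not have separated stage from an effect of nck2. RNA degradation in the nck2 samples also stays open, since the GAPDH ratio was higher in nck2 while the acta1 ratio, 3.75 in nck2, overlapped between the groups.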

How the results depend on the processing

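Cyclic loess and the removal of probe sets that match several transcripts were chosen only after the results were seen. Over all alternatives, 319 values of the named genes kept their direction and their call, 4 lost the call (all of vaspb) and 0 reversed. A value was counted only where the alternative kept the probe set, and the named genes were chosen for large differences past the threshold in these data. Their stability therefore says little about other changed probe sets. The count of changed probe sets was 1307 (456 higher) without the variance trend, and median centring gave 1878 higher and 718 lower. Leaving out 1 array gave 571 to 2346 changed probe sets, 270 to 924 higher and 301 to 1422 lower, the lowest without control array A and 639 without control array B, where the lone array is assumed to vary like the other group. With the hybridization letter as a replicate block 2461 probe sets changed, 2162 of them shared with the fit without it, and the A minus B differences of the groups correlated at -0.0364 across probe sets, so the letters were not taken as pairs. The number of lists that shifted was 0 with an estimated correlation and 20 with fry. The ribosomal list reversed to -0.12 with cyclic loess (adjusted p = 2.5e-05), which removes a trend on brightness. With the deposited scaling its median of 0.051 lay at percentile 0.34 of random lists matched on mean level, whose median was 0.14. Neither the p-value nor the random lists allow for the estimated correlation of 0.80 between ribosomal genes, so both may overstate the evidence. The nck2a difference passed with median centring, at 0.47, which raises every difference. Leaving out 1 array, the brighter nck2b probe set ranged from -0.064 to 0.45, with -0.028 without nck2 array B, and nck1b from -0.042 to 0.16. The mean replicate correlation was 0.949 with no filter and 0.987 with the 60th percentile filter. Where both arrays of a group lay below background, as for phlda3, lnx1, egln3, pck1 and 1 of the fosab probe sets, only a lower bound of the fold could be given.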

Other observations

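All gene families in this part and their examples were chosen after seeing the data, by the shared start of their symbols, and 78 families of at least 8 genes were tested, of which 13 shifted up and 5 down. Some of them share genes with lists described above, so these counts are not independent of those lists. Among these are psmb and psmd (proteasome), ndufa, ndufb and cox (oxidative phosphorylation), and sox, her and hoxb (neural progenitors). Genes of the mitochondrial large ribosomal subunit (mrpl) shifted up, 18 of 38 higher and 0 lower with a median of 0.39 (camera adjusted p = 1.3e-07, adjusted p = 0.683 with an estimated correlation). Among them mrpl12 rose by 1.06 (SE 0.12) and mrpl27 by 0.65 (SE 0.12). The timm and tomm families, which encode subunits of mitochondrial import complexes, shifted up as well, with 5 of 8 timm genes higher at a median of 0.55 and 4 of 8 tomm genes higher at a median of 0.40 (camera adjusted p = 0.000318 and 0.00246, adjusted p = 0.683 with an estimated correlation for both). RNA polymerase subunits (polr) had 6 of 19 higher and 0 lower, with a median of 0.32 (camera adjusted p = 0.000734, adjusted p = 0.683 with an estimated correlation).

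Families that shifted down included histone lysine demethylases and developmental transcription factors. Of 8 kdm genes 4 fell and 0 rose, with a median of -0.52 (camera adjusted p = 0.00495, adjusted p = 0.683 with an estimated correlation), among them kdm5bb, at -0.86 (SE 0.10), and kdm5ba, at -0.68 (SE 0.10). Of 8 her genes, which encode transcriptional repressors related to Hairy and Enhancer of split, 4 fell and 0 rose, with a median of -0.45 (camera adjusted p = 0.0408, adjusted p = 0.683 with an estimated correlation), and her4.5 and her8a differed by -1.21 (SE 0.15) and -0.95 (SE 0.14). The probe sets of her4.5 and of her4.2, which also fell, can match several transcripts, so their calls may not be independent. Of 12 hoxb genes 4 fell and 0 rose, with a median of -0.35 (camera adjusted p = 0.0249, adjusted p = 0.683 with an estimated correlation). The directions of these families held with quantile normalization, median centring and cyclic loess. Over these and the deposited scaling, the median nearest 0 was -0.17 for hoxb, -0.28 for her and 0.32 for polr.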
